A study of Mus musculus with 7 samples.

How the data were processed

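Gene expression was measured by 3′-end RNA sequencing in 7 libraries of EpCAM-positive cholangiocytes, the epithelial cells of the bile ducts, sorted from livers of Foxp3-GFP-DTR mice. In these mice the receptor for diphtheria toxin is made in Foxp3-positive regulatory T cells, so that the toxin is used to remove them. Per the labels, all animals ate a diet with DDC, a chemical that injures bile ducts, for 10 days, with an intraperitoneal injection of saline (PBS, 4 libraries) or of diphtheria toxin at 1 µg/kg (DT, 3 libraries) every 48 h. Per the labels' protocols, total RNA was made into libraries with a QuantSeq FWD kit, which reads the 3′ ends of transcripts. The deposited values are raw read counts per gene symbol, not normalized, and the genome build was mm9 per the submitters' processing notes. The aligner, the counting tool, the annotation and any use of molecular identifiers are not given in the sources used here. Groups and replicate numbers came from the sample titles. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be partly technical.

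The count table held 24552 gene symbols, of which 11487 had a count above 0 in at least 1 library. Total counts per library ran from 4805018 to 6285624. Library sizes were scaled by TMM, and the filterByExpr function of edgeR 4.0.16 (R 4.3.3) kept 7688 genes, which held 97.5% of all counts. DT was compared with PBS by the edgeR quasi-likelihood F test with robust dispersion, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. CPM values were computed on the TMM-scaled library sizes and are given as mean ± SD. The SE of a log2 fold change was taken from the fold change and the F statistic. For a gene at 0 in all libraries of a group, the fold was set against a floor of 3 counts per library. Intervals and floors cover counting error only, since reads made by PCR are not independent molecules.

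Before the data were examined, 40 gene lists were fixed for pathways, responses and cell types. Lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Each list was also tested by camera with an estimated correlation and by fry, and its members were adjusted over the list alone. The genes named were set by a rule fixed at the same time. It took genes past the threshold with an average log2 CPM of 3 or more and no overlap between the groups (up to 10 per direction), or the 5 with the smallest p where none passed in a direction. It also took up to 4 members with the smallest adjusted p of each list that passed, up to 2 passing members of any other list, and a set of genes chosen in advance, among them Foxp3, Epcam and Ccn2, which the table lists as Ctgf. A gene that this rule takes is not reported here, though it stayed in every test. Other genes named here were chosen after their values were seen, and this is said beside them.

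The scripts were tested on simulated counts for 7688 genes, drawn with the fitted means and dispersions and the library sizes of these libraries. In the gene tests the filter kept 6491 to 6535 of the simulated genes, so these counts do not fully match the data. Changed genes that the filter removed count as not recovered. Of 200 genes changed by a log2 fold of 1, 0% were recovered, both among all tested genes and among genes with an average log2 CPM of 8 or more. At a log2 fold of 2, recovery was 2% among all tested genes and 17.5% among genes at that higher level, with 2 unchanged genes called in the latter test. A simulated list of 40 genes shifted by a log2 fold of 1 had an unadjusted camera p below 0.05 in 14 of 20 draws, and an unshifted list in 0 of 20. Here the genes varied independently and p was not adjusted over the lists. The draws therefore do not give the recovery or the false calls of the list test used on the data.

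Alternatives planned before the data were examined were RLE and upper quartile factors, no filter on low counts, a filter at an average log2 CPM of 3, the replicate number as a block, hepatocyte and leukocyte marker scores as covariates, limma-voom with sample weights, DESeq2 1.42.0, and leaving out each library. A filter at an average log2 CPM of 8, the presence of Y-linked reads as a covariate and removal of the ribosomal RNA row Rn45s were chosen after seeing the data. Gene length, used in 1 check, came from a GRCm38 annotation, another build than that of the counts, so no coordinates are given. That annotation held 24030 of the 24552 symbols. Figures were drawn with matplotlib 3.10.9.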

Results

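Expression was compared between cholangiocytes of DDC-fed mice given diphtheria toxin, which targets regulatory T cells in this strain (DT, n = 3), and those of DDC-fed mice given saline (PBS, n = 4). The comparison asks how bile duct epithelium responds during cholestatic injury when Foxp3-positive cells are targeted. The depletion itself was not measured in these libraries. Total counts were 4940336, 5175040, 4805018 and 5499832 in PBS 1 to 4 and 5683824, 5765651 and 6285624 in DT 1 to 3. The libraries held counts above 0 for 5419 (DT 1) to 8361 (PBS 4) genes. Counts of 0 were frequent even for moderately expressed genes. Where the other libraries of a group averaged 100 to 200 counts, 43.5% of values were 0, and at 1000 to 2000 counts 1.17% were. The median coefficient of variation between libraries was 105% in PBS and 96.3% in DT for genes at 20 to 100 CPM, and 25.3% and 21.8% for genes at 500 CPM or more.

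**Figure D1:**
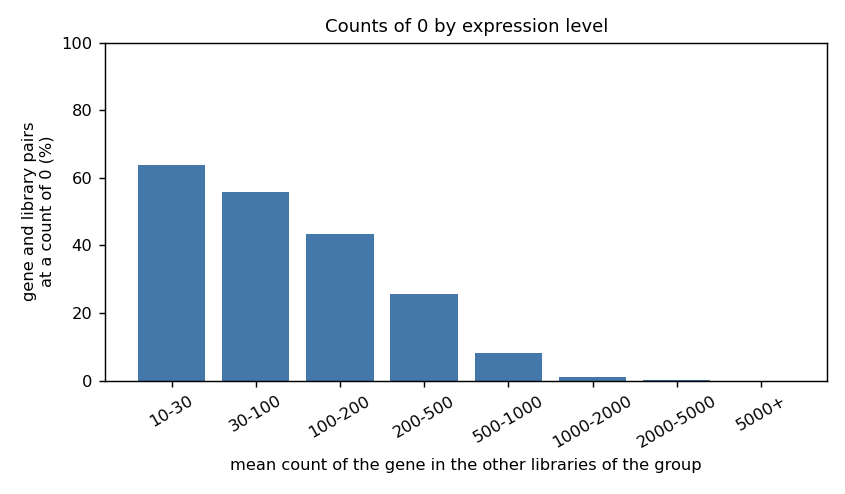
Percent of gene and library pairs with a count of 0 (y axis) by the mean count of the gene in the other libraries of its group (x axis), over all 7 libraries. The share falls from 63.7% at a mean of 10 to 30 counts to 0% at 5000 or more.

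Malat1, Rsrp1 and Erdr1 fell in DT by the edgeR test, and no gene passed it as higher. Malat1, a long non-coding RNA held in the nucleus, went from 13385 ± 1153 CPM in PBS (SD, n = 4) to 6519 ± 353 CPM in DT (SD, n = 3), a log2 fold change of -1.04 (SE 0.15, edgeR adjusted p = 1.01e-04). Its share of all counts was 1.32% in PBS and 0.627% in DT. Rsrp1, which encodes an arginine- and serine-rich protein, went from 1099 ± 198 to 353 ± 106 CPM, a log2 fold change of -1.64 (SE 0.33, edgeR adjusted p = 0.0308). Erdr1 had 1332, 1662, 574 and 505 counts in PBS 1 to 4 and 0 counts in each DT library (edgeR adjusted p = 2.28e-04). Against the floor of 3 counts per library this was 379-fold lower. That value is no lower bound, since the floor covers counting error only. Where the other libraries of a group averaged 200 to 500 counts, 25.6% of values were 0. For each of the 3 genes every DT library lay below every PBS library.

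Of 7688 genes tested by edgeR, 0 passed as higher and 3 as lower, with 107 higher and 162 lower at an unadjusted p below 0.05, while DESeq2 called 47 higher and 136 lower and limma-voom with sample weights 6 and 6. Rsrp1 did not pass without PBS 1, PBS 2, PBS 3, PBS 4 or DT 1 (edgeR adjusted p = 0.132, 0.175, 0.519, 0.365 and 0.192), Erdr1 did not pass without PBS 1 or PBS 2 (0.0580 and 0.588), and Malat1 passed in all 7 of these fits but, like Erdr1, not by limma-voom (adjusted p = 0.837 for Malat1 and 0.0762 for Erdr1).

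**Figure D2:**
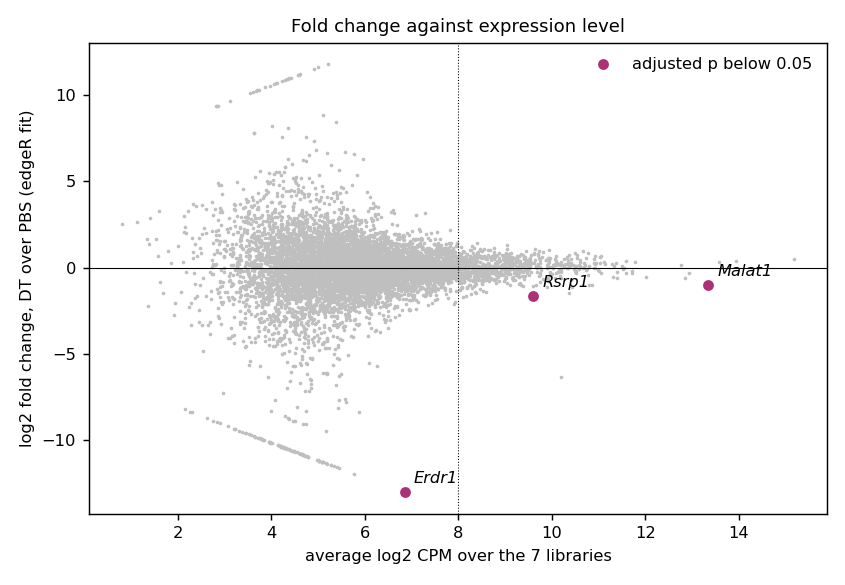
Fitted log2 fold change of DT over PBS (y axis) against average log2 CPM over the 7 libraries (x axis) for the 7688 tested genes, with the 3 genes past adjusted p 0.05 marked and a dotted line at 8. Diagonal streaks are genes at 0 in all libraries of 1 group, whose fitted values are no measured folds, Erdr1 included.

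The 5 genes with the smallest p among those with higher values in DT did not pass the edgeR test. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, was at 1147 ± 310 CPM in PBS and 2259 ± 550 CPM in DT (log2 fold change 0.98, SE 0.26, edgeR adjusted p = 0.419). The log2 fold changes of Dbi, Rps20, Scara3 and Anxa5 were 0.84, 1.02, 1.29 and 0.87 (edgeR adjusted p = 0.642, 0.642, 0.748 and 0.796). These 4 passed by DESeq2 (adjusted p = 0.00577, 0.00505, 0.0245 and 0.00219), and Dbi and Anxa5 also by limma-voom (adjusted p = 0.0201 and 0.00551). Each of the 5 had higher CPM in all 3 DT libraries than in all 4 PBS libraries. Among genes with an average log2 CPM of 8 or more, 95 of 733 (13.0%) had no overlap between the groups, where chance gives 5.71% of independent genes and another split of the libraries, PBS 1 to 3 against the rest, gave 96.

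**Figure D3:**
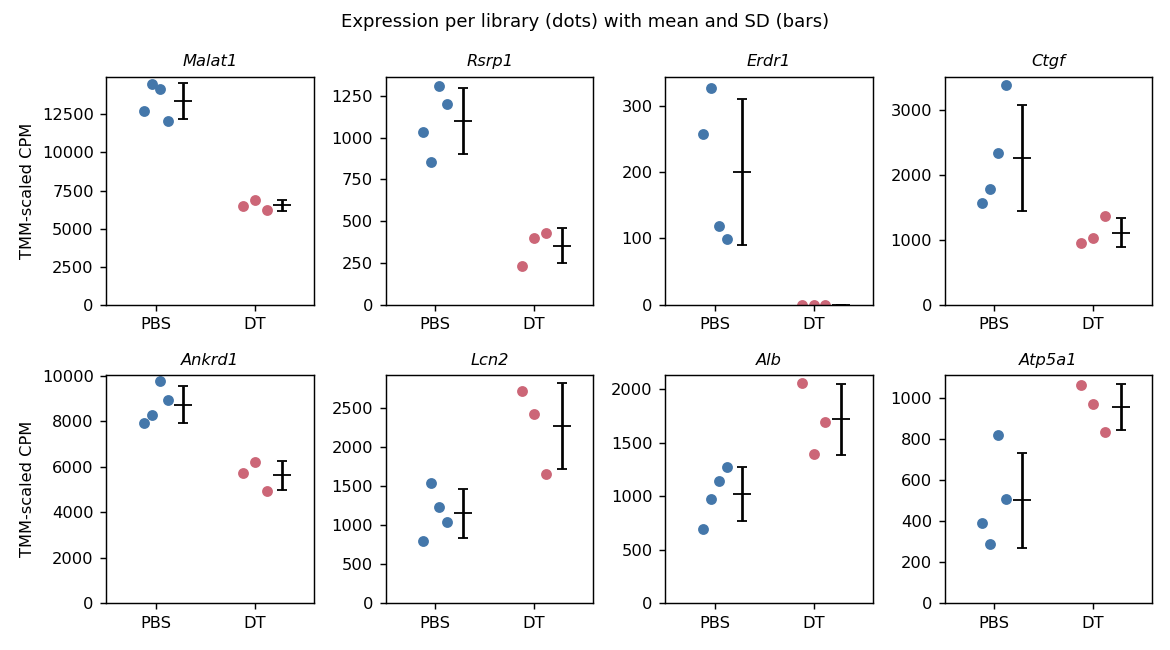
TMM-scaled CPM of 8 genes in each PBS (n = 4, blue) and DT (n = 3, red) library, with mean and SD as black bars. Malat1, Rsrp1 and Erdr1 passed the edgeR test, and Ctgf, Ankrd1, Lcn2, Alb and Atp5a1 did not.

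Bile duct genes chosen in advance did not pass the test in either direction. Epcam, the marker used for sorting, was at 876 ± 173 CPM in PBS and 743 ± 99.5 CPM in DT, and Krt7, a duct keratin, at 234 ± 78.3 and 200 ± 74.3 CPM. Krt19, another duct keratin, was at 410 ± 58.2 and 627 ± 300 CPM, the duct transcription factor Sox9 at 1162 ± 131 and 1902 ± 847 CPM, and Spp1, which encodes osteopontin, at 11098 ± 1856 and 13745 ± 1811 CPM. The cholangiocyte identity list of 32 tested genes had 17 with positive and 15 with negative fold changes, a median log2 fold change of 0.01 and 0 members past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.988). Its genes made up 3.51% to 3.72% of the counts of each library. The cell cycle marker Mki67 (log2 fold change -1.57, SE 3.31), the cell cycle inhibitor Cdkn1a (0.60, SE 0.48), the checkpoint ligand Cd274 (0.25, SE 3.30), the MHC class II gene H2-Ab1 (0.50, SE 1.89) and the chemokine Cxcl10 (-0.60, SE 1.20) each had an edgeR adjusted p of 1.00. H2-Ab1 had 0, 12, 7 and 1279 counts in PBS 1 to 4 and 635, 385 and 536 in DT 1 to 3, and its log2 fold change was 6.13 without PBS 4. Mki67 had counts in PBS 3, PBS 4 and DT 3 alone (188, 518 and 202). When 1 library was left out, the log2 fold change of Krt19 (0.61) was lowest without DT 1 (0.17) and that of Cdkn1a without DT 2 (0.14). Foxp3 had 0 counts in all 7 libraries, which by counting error alone allows up to 3 counts in each. The true limit is higher, since 43.5% of values were 0 even at means of 100 to 200 counts.

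The cholesterol synthesis, oxidative phosphorylation, hepatocyte marker and MHC class I presentation lists passed as higher in DT by the camera test on the edgeR fit with a preset correlation, and no list passed as lower. None of the 4 passed with an estimated correlation (adjusted p = 0.473, 0.473, 0.521 and 0.473 with an estimated correlation), and 0 of their members passed on their own. Of 20 tested cholesterol synthesis genes 16 had positive fold changes, with a median log2 fold change of 0.92 (camera adjusted p = 0.00637). Hmgcs1, which makes HMG-CoA, was at 132 ± 59.1 CPM in PBS and 360 ± 83.4 CPM in DT, and the log2 fold changes of Sqle and Cyp51 were 1.23 and 0.81. Of 40 tested oxidative phosphorylation genes 31 were positive, with a median of 0.54 (camera adjusted p = 0.0113). Atp5a1, the ATP synthase alpha subunit, was at 499 ± 231 and 955 ± 114 CPM, and Cox7a2, Sdha and Cox7b had log2 fold changes of 1.28, 1.96 and 1.67 (SE 0.47, 0.77 and 0.68). Without DT 1 the values of Cox7a2 and Cox7b were 0.71 and 0.85.

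Of 17 tested MHC class I presentation genes 13 were positive, with a median log2 fold change of 0.65 (camera adjusted p = 0.0442; adjusted p = 0.473 with an estimated correlation). B2m, the MHC class I light chain, was at 1610 ± 729 CPM in PBS and 2300.5 ± 358 CPM in DT (log2 fold change 0.51, and 0.27 without PBS 1), and Canx, Psme1 and Psmb10 had log2 fold changes of 0.71, 1.01 and 3.41 (SE 0.45, 0.65 and 2.71). Psmb10 had 133, 0, 37 and 0 counts in PBS 1 to 4, and its value was 5.11 without PBS 1. The class I heavy chain genes H2-K1 and H2-D1, chosen after their values were seen, had log2 fold changes of -0.17 and 0.09. With the filter at an average log2 CPM of 8 the list did not pass (camera adjusted p = 0.546). Of 34 listed hepatocyte markers 11 were tested, 8 of them positive and 3 negative. Their median log2 fold change was 0.75 (camera adjusted p = 0.0442, and adjusted p = 0.521 with an estimated correlation). The hepatocyte gene Apoa1 was not tested and was chosen after its values were seen. It went the other way, with 186, 0, 0 and 41 counts in PBS 1 to 4 and 0 in each DT library. Alb, which encodes albumin, was at 1022 ± 251 and 1719 ± 332 CPM, and Serpina1b, Fgb and Gc had log2 fold changes of 3.00, 1.32 and 0.45 (SE 1.96, 1.43 and 0.36). Serpina1b had 0 counts in PBS 1 and PBS 4, Fgb was at 0.26 without DT 1, and Gc was at 0.13 without DT 3. With the hepatocyte score as a covariate Gc was at -0.29, but Gc is itself part of that score. Hepatocyte markers made up 0.226% to 0.356% of counts in PBS libraries and 0.395% to 0.501% in DT libraries. No member of these 4 lists passed over all genes or adjusted over the list alone, and the named members had an edgeR adjusted p of 1.00. None of the 4 passed with the presence of Y-linked reads as a covariate or by fry, and the MHC class I and hepatocyte lists were lost in 14 of 20 and 12 of 19 alternatives. The alternatives include the hepatocyte score, which is built from the hepatocyte list and so cannot test that list. Oxidative phosphorylation did not pass without DT 1 (camera adjusted p = 0.0520), with the leukocyte score as a covariate (0.0779) or no filter on low counts (0.0523). MHC class I did not pass without PBS 1, PBS 3, DT 1, DT 2 or DT 3 (0.0752, 0.0978, 0.483, 0.184 and 0.0696), nor hepatocyte markers without PBS 1, PBS 2, DT 1, DT 2 or DT 3 (0.107, 0.169, 0.0520, 0.277 and 0.106).

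**Figure D4:**
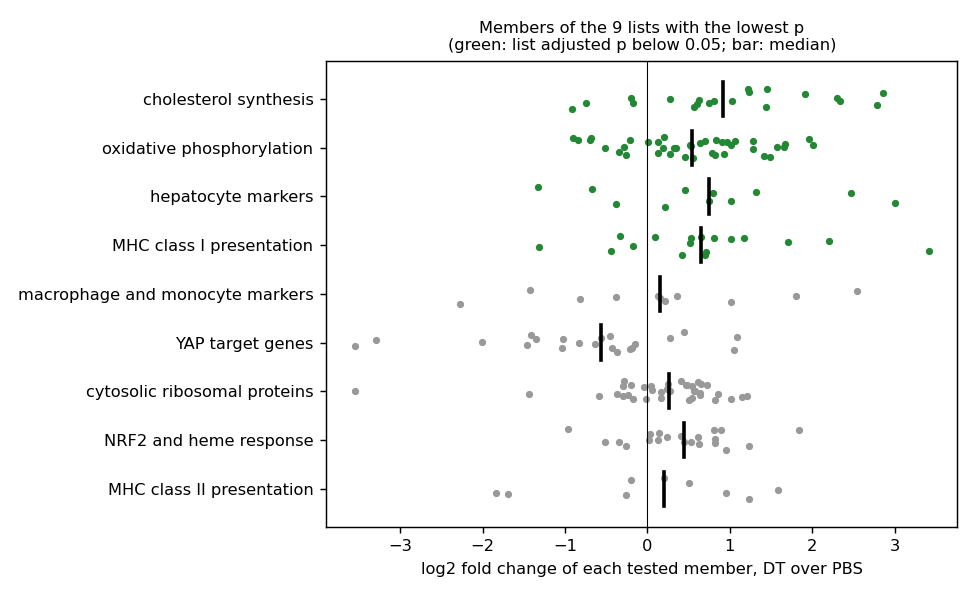
Log2 fold change of DT over PBS (x axis) for each tested member (point) of the 9 lists with the lowest camera p, with the median as a bar and the 4 lists past adjusted p 0.05 in green. Medians run from -0.56 for YAP targets to 0.92 for cholesterol synthesis.

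YAP target genes, which respond to a co-activator of Hippo signalling, had negative fold changes in 17 of 21 tested members, with a median log2 fold change of -0.56, and did not pass as a list (camera adjusted p = 0.115), but passed as lower by limma-voom (0.01004). On the edgeR fit it had an adjusted p = 0.594 with an estimated correlation. None of them passed over all genes, and 3 were lower when adjusted over the list alone. Ctgf (Ccn2), a matricellular protein gene, was at 2261 ± 813 CPM in PBS and 1109 ± 218 CPM in DT (log2 fold change -1.03, SE 0.26, edgeR adjusted p = 0.375). Ankrd1, chosen after its values were seen, was at 8728 ± 820 and 5622 ± 645 CPM (-0.63, SE 0.16, edgeR adjusted p = 0.375). In the immediate early list of 25 tested genes, 0 passed over all genes and 2 were lower when adjusted over the list alone (camera adjusted p = 0.328). Dusp1, a MAP kinase phosphatase gene, and Junb, an AP-1 subunit gene, both chosen after their values were seen, had log2 fold changes of -1.03 and -1.11 (edgeR adjusted p = 0.288 for each). By DESeq2, Ctgf, Ankrd1, Dusp1 and Junb passed as lower (adjusted p = 0.00112, 0.00126, 3.28e-05 and 4.19e-05).

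Other lists near the threshold were macrophage and monocyte markers (7 of 11 tested members positive, camera adjusted p = 0.106), cytosolic ribosomal proteins (26 of 38 positive, 0.115), NRF2 and heme response (17 of 21 positive, 0.134) and MHC class II presentation (5 of 9 positive, 0.168). Without PBS 4, a library with more macrophage and MHC class II reads than PBS 1 to 3, these 4 lists passed as higher (camera adjusted p = 0.0116, 0.0433, 0.0297 and 0.0194, with the preset correlation), and the macrophage list also passed without DT 3 (0.0389). On the 7 libraries each of the 4 had an adjusted p = 0.594 with an estimated correlation. With all 7 libraries, ribosomal proteins and NRF2 and heme response passed as higher by limma-voom (0.00217 and 0.0415, with the preset correlation). When adjusted over the list alone, 1 ribosomal protein gene was higher and 1 lower, and in the list of genes responsive to STAT3, IL-17 and IL-22 1 was higher. The other 22 of the 31 tested lists had camera adjusted p from 0.240 to 0.988. Among them were interferon-gamma response (0.496), G2 and M phase (0.389), S phase (0.612), p53 targets and senescence (0.880), Notch pathway (0.749), and chemokines and cytokines (0.910). The remaining 9 lists had fewer than 5 tested genes. Of 20 listed B and plasma cell markers, the 15 in the count table had 0 counts in every library. Of 33 listed T and NK cell markers, the 30 in the count table had 0 to 822 counts per library.

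The libraries also differed in sex-linked genes, chosen after their values were seen. Xist, the RNA of the inactive X chromosome, had 630, 12089, 17627 and 10420 counts in PBS 1 to 4 and 453, 0 and 0 in DT 1 to 3. Y-linked genes had 2048, 0, 0 and 0 counts in PBS 1 to 4 and 1681, 1045 and 880 in DT 1 to 3. Y-linked reads were thus present in all 3 DT libraries and in 1 of 4 PBS libraries. PBS 1 and DT 1 held both Xist and Y-linked reads, so the presence of Y-linked reads may not give the sex of a single animal. PBS 4 held 1522 counts of the macrophage gene Lyz2, also chosen after its values were seen, against 6, 8 and 0 in PBS 1 to 3 and 81, 69 and 330 in DT 1 to 3.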

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

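Among the 52 values tested for a library far from the others of its group, 3 stood apart, where 2.6 are expected by chance, each in the PBS libraries. For Anxa5 the gap between PBS 4 (1428 CPM) and the nearest other PBS library was 0.892 of the range of the group. For H2-Ab1 the share was 0.991, with 1279 counts in PBS 4 and 0, 12 and 7 in PBS 1 to 3. For Cd274 it was 1, with 336 counts in PBS 4 and 0 in each of PBS 1 to 3.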

How the results depend on the processing

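The 3 lower genes were called with RLE and upper quartile factors, and scaling moved the median log2 fold change of highly expressed genes by less than 0.1. That median was -0.10 with the hepatocyte score and 0.14 with the Y-linked covariate, against 0.03. Genes higher and lower numbered 1 and 7 with no filter, 6 and 6 by limma-voom, and 47 and 136 by DESeq2, of which 134 had a whole group at 0. With the filter at an average log2 CPM of 3, which kept more genes (8797) and so was looser, 1 was higher. Of the alternatives chosen after seeing the data, the filter at 8 gave 5 lower genes and the Y-linked covariate 23 higher. With the replicate number as a block, 6 were higher and 6 lower, all 3 calls kept. To look for pairs, log2 CPM values of 733 highly expressed genes were taken as deviations from the mean of their group. These deviations correlated at -0.0600 to 0.0251 between same-numbered libraries, with 0 of 3 pairs over 0.1. Of the DT libraries, 1 correlated best with its own number. Leaving out 1 library gave 0 to 1 higher and 1 to 4 lower genes.

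Lists higher in DT numbered 2 with upper quartile factors, 1 with no filter, 2 with the filter at 8, 2 with the leukocyte score, 0 with the Y-linked covariate, 0 with an estimated correlation, 0 by fry, 5 by limma-voom and 6 with the replicate block. With the block, MHC class I was lost (camera adjusted p = 0.0666), and macrophage markers (0.00204), NRF2 and heme response (0.0359) and MHC class II (0.0359) passed. They ranged from 1 (without DT 1) to 8 (without PBS 4) when 1 library was left out. With the filter at 8, with the hepatocyte score and by limma-voom, 1 list was lower, which was YAP targets with the filter at 8 and by limma-voom (camera adjusted p = 0.00128 and 0.01004, range over alternatives 0.00128 to 0.594). The sign turned for Gc (-0.29), Krt7 (0.0009), Cdkn1a (-0.37) and Cd274 (-2.31) with the hepatocyte score, of which Gc is itself a part. It also turned for Epcam (0.086) and Mki67 (8.98) with the Y-linked covariate. Cd274 ran from -3.54 to 0.82 when 1 library was left out. Except for fewer libraries or genes tested, the cause was not tested. The frequent counts of 0 limit what can be seen below about 1000 counts.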

Other observations

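The tests of sex, of dilution by ribosomal RNA, of genes at 0 in a whole group, of genes with no overlap and of the correlation with gene length were chosen only after the results were seen. Of the 183 genes called by DESeq2, 34 had reads in every library, 10 higher and 24 lower in DT. Among these, chosen after their values were seen, the cytoskeleton and adhesion genes Zyx and Iqgap1 had log2 fold changes of -1.83 and -0.94 (DESeq2 adjusted p = 0.0369 and 0.0177). The kinase genes Map4k4 and Mapk7 had -1.16 and -5.63 (DESeq2 adjusted p = 0.00505 and 0.00445), and the histone methyltransferase gene Kmt2a had -2.19 (0.00307). Among the 10 higher were Anxa5 (0.85, DESeq2 adjusted p = 0.00219), Dbi (0.85, 0.00577) and the transglutaminase gene Tgm2 (0.94, 0.0423). The YAP target Amotl1 had -1.46 (0.0248). None of the genes named so far in this paragraph passed the edgeR test. Ctgf, Ankrd1, Dusp1 and Junb, described above, were also among the 34, as were Malat1 and Rsrp1, which did pass it.

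Of the 35 splits of the 7 libraries into 3 and 4, only the real 1 gave 3 called genes, and the highest of the others gave 0. That argues against chance for this count but does not exclude it, since 1 of 35 is the smallest share these libraries can give. For lists chance stays open: 2 of 35 splits gave as many as the real 4, and PBS 1, PBS 2 and PBS 3 against the rest gave 5. Chance also stays open for the 64 genes read in all libraries of a group and at 0 in the other, since 14 of 35 splits gave as many. PBS 1, PBS 3 and DT 1, with the fewest detected genes of all libraries, gave 185. The same holds for the 95 highly expressed genes with no overlap between the groups, since 2 of 35 splits gave as many, with 96 for PBS 1, PBS 2 and PBS 3 against the rest. The split with 185 points to a structure of the libraries. Longer genes tended to have lower fold changes across 731 highly expressed genes (Spearman's rho -0.23, across genes, which are not independent replicates), and 3 of 35 splits gave a rho as extreme.

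Malat1 and Rsrp1 fell together. The nuclear RNAs Neat1 and Kcnq1ot1, chosen after their values were seen, had log2 fold changes of -1.06 and -1.07. Neither passed the edgeR test (adjusted p = 0.920 for Kcnq1ot1 and higher for Neat1), though they passed by DESeq2 (adjusted p = 0.0339 for Neat1 and 0.00302 for Kcnq1ot1). Ribosomal RNA made up 4.23% of counts in DT and 3.10% in PBS, and its dilution of other transcripts, at most -0.0302 on the log2 scale, is argued against as the cause, while removal of the Rn45s row moved nothing and so decided nothing (2 of 2 genes passed). A lower share of nuclear RNA stays open: 21 tested nuclear transcripts not looked at before had a median of -0.0342 (quartiles -0.52 to 0.16), with 11 negative. Sex stays open too, as 1 of the 2 genes passed with the Y-linked covariate (Malat1 -0.97, Rsrp1 -1.55 with edgeR adjusted p = 0.172), and PBS 1 alone separates sex from treatment. The toxin's action on regulatory T cells is a further candidate explanation, which the design cannot part from these.

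The absence of Erdr1 reads from DT is hard to place. Chance loss of reads is argued against, since among 667 genes with similar counts in PBS 7.74e-04 genes are predicted at 0 in all DT libraries, and 0 others were. The prediction takes the loss as independent between libraries, which was not tested. With the Y-linked covariate Erdr1 passed (edgeR adjusted p = 0.00107, range over alternatives 3.77e-14 to 0.588), which met the bound set for arguing against sex. That bound is not relied on, because PBS 1 is the only PBS library with Y-linked reads and carries the whole estimate. Sex and treatment thus cannot be told apart here. PBS 1 also held 630 counts of Xist, so its Y-linked reads may not give its sex. A difference in genotype or litter between the animals was not tested.

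For the higher cholesterol synthesis and oxidative phosphorylation lists, a general shift between short and long genes is argued against, as 0.02% of random lists matched on expression and length had a median as high as that of oxidative phosphorylation. RNA from hepatocytes stays open as a cause. With the hepatocyte score as a covariate 2 of these 2 lists passed, narrowly (camera adjusted p = 0.0483 and 0.0412 with the preset correlation). Without the score each had a camera adjusted p = 0.473 with an estimated correlation. Medians were 0.81 and 0.52 with the score, against 0.92 and 0.54. The score does not fully follow the hepatocyte share of counts, so passing with it cannot exclude this cause. DT 1 had a lower score (-0.37) than PBS 3 (0.41) and PBS 4 (0.14). Yet hepatocyte markers made up 0.395% of counts in DT 1, above the 0.356% in PBS 4. The hepatocyte list itself was higher in DT. Sex stays open: with the Y-linked covariate neither list passed (camera adjusted p = 0.420 and 0.431), which met the bound set for sex as the cause. The oxidative phosphorylation median went from 0.54 (quartiles 0.09 to 1.02) to 0.9231 (-0.08 to 2.33). That of cholesterol synthesis went from 0.92 (0.49 to 1.57) to 1.84 (0.13 to 9.93). The calls thus ended with a wider spread and not a smaller fold. PBS 1 alone carries these estimates, so neither the bound nor the folds are relied on. Chance also stays open for the lists, as above, and a response to the toxin or to the loss of regulatory T cells may be among the explanations.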
